A study of Homo sapiens with 6 samples.

How the data were processed

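Messenger RNA from MDA-MB-231, a human breast cancer cell line of mesenchymal character, was sequenced in 6 libraries. The labels number 3 libraries Con and 3 libraries Ang, and the group of each library was taken from that label. The series design says that breast cancer cells were exposed to exosomes, the small vesicles released by cells, from normal or from hypertrophic cardiomyocytes. No label says what Con and Ang stand for, so the groups are called by their labels throughout. No label says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

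Per the labels' protocols, messenger RNA was selected on poly-T beads, fragmented and primed with random oligonucleotides. The second strand was made with DNA polymerase I and RNase H, and the libraries were amplified in 15 PCR cycles. The protocol names no step that marks the strand of the RNA. The authors deposited one table of whole-number read counts per Ensembl gene ID for each library. Per the submitters' processing notes, the tools were HTSeq 0.9.1, a read counter, and DESeq 1.39.0, with genome build GRCh38. The aligner, the annotation release and the strand setting of the counter are not given in the sources used here.

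The files held 28979 gene IDs, of which 28918 were matched to a gene symbol and 28192 to GENCODE release 29 on GRCh38, which gave gene types, coordinates, exons and 3′ untranslated regions. No row was a summary row without a gene. Total counts per library ran from 3369212 to 5437190. A count of 0 allows up to 3 counts at the 95% level, which is 0.552 to 0.890 CPM, the count scaled to the library total, in these libraries. PCR reads without molecular identifiers are not independent molecules, so this limit and the exact binomial (Clopper-Pearson) intervals of ratios of low counts cover counting error only. No 2 libraries held identical values. The chi-square per gene between libraries of a group was 3.62 to 14.6, so no pair agreed within sampling noise.

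The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and Ang was tested against Con with the robust quasi-likelihood test without a replicate term. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and a further count required a fold change of at least 2. Log2 fold changes are Ang minus Con. CPM values are TMM scaled and given as mean ± SD over the 3 libraries of a group, and log2 fold changes are given ± SE.

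A set of 38 gene lists was fixed for this cell line and exposure, and 33 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Camera compares a list with all other tested genes. Camera with an estimated correlation and fry, which asks whether the members move one way on balance, were run beside it. Seed sites of 27 microRNAs or microRNA families known from heart muscle, hypertrophy or vesicles were searched in the longest annotated 3′ untranslated region of each gene. Genes with a site were compared with the other genes by camera, and their median was ranked among up to 1000 random 7-mers of the same GC and CpG content.

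Genes were named by a fixed rule. As fewer than 8 genes passed the threshold, the 8 genes with a symbol and the smallest unadjusted p were named, as not past it. Up to 4 members of a called list and up to 2 of a list not called were taken by smallest p. The 5 most abundant genes and the detected renin-angiotensin genes were added. The values of 1 gene that the rule names are not reported here. Groups, tests, lists, the naming rule and the alternatives listed first below were set before the data were examined.

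To describe strand, GENCODE 29 exons of the 2 strands were intersected with bedtools 2.31.1. Pairs were formed of a non-coding gene with at least 90% of its exon bases under exons of 1 protein-coding gene on the other strand and no exon overlap on its own strand. The coding gene needed at least 300 counts over all libraries, and 0.5 was added to each count before the ratio of counts per base was taken.

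The fits and set tests were tested on simulated counts for the 14547 tested genes of this comparison, drawn from the real means, library sizes and dispersions, with 200 changed genes in each of 5 runs. The test called 44.2% of genes changed 2-fold and 86.8% of genes changed 4-fold. Among genes of at least 50 CPM it called 93.8% and 100%. False calls were 5.35% of calls. A list shift of 0.5 and a seed shift of -0.2 on the log2 scale were called in 5 of 5 runs each.

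The alternatives set beforehand were relative log expression (RLE) scaling, no low-count filter, a filter of at least 1 CPM in 3 libraries, a replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, the other set tests, 8mer sites alone and a correction for length and GC content of the 3′ untranslated region. Alternatives chosen after seeing the data were a term for the strand ratio of each library, genes free of opposite-strand exon overlap, library quality weights, Con replicate 2 left out together with the strand ratio term, and an estimated correlation for lists in such fits. The planned pseudocount alternatives were for normalized values and were not run, since the files hold counts.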

Results

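The data were read counts per gene from 6 RNA sequencing libraries of MDA-MB-231 breast cancer cells, 3 labelled Con and 3 labelled Ang. Total counts were 4807007, 5437190 and 3369212 in Con replicates 1 to 3, and 3482629, 3961442 and 3596124 in Ang replicates 1 to 3. Between 21145 and 22778 genes had at least 1 count in a library, and 16596 genes were detected in all 6.

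The 5 most abundant genes were noncoding or pseudogene loci and BEST1, each with exon bases under another gene on the other strand. They were led by ENSG00000230021, a transcribed pseudogene on chromosome 1 (586071 to 827796), at 48071 ± 8591 CPM in Con and 50431 ± 1647 CPM in Ang. Its exons overlap, among others, the mitochondrial pseudogene MTCO2P12 on the other strand. ENSG00000278791, a microRNA gene that lies wholly under the mitochondrial pseudogene MTCO1P12 on the other strand, had 21328 ± 5395 CPM in Con and 24906 ± 1049 CPM in Ang. As 0 mitochondrially encoded genes were matched in the files, reads that these loci may share with them could not be examined. TSIX, a long noncoding RNA gene on chromosome X, had 14186 ± 3930 and 14385 ± 827 CPM. ENSG00000269968, an antisense gene wholly under exons of GAPDH, the glycolytic enzyme gene, had 11546 ± 1766 and 13017 ± 708 CPM. BEST1, whose exons overlap FTH1, the ferritin heavy chain gene, on the other strand, had 10590 ± 1984 and 11373 ± 618 CPM. None of these 5 differed between groups by the edgeR quasi-likelihood test.

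Protein-coding genes held fewer counts per base than the non-coding genes lying under them on the other strand. Over 250 such pairs, the median ratio of counts per base, non-coding over coding gene, was 32.5, with quartiles of 5.86 and 62.9, and 88.8% of the pairs were above 1. The library medians were 39.3, 23.2 and 41.1 in Con replicates 1 to 3, and ran from 32.9 to 35.4 in the Ang libraries. For GAPDH the ratio was 82.5, for TPT1, the translationally controlled tumour protein gene, it was 105, and for P4HB, a protein disulfide isomerase gene, it was 78.4. Con replicate 2 had the lowest ratio and the largest share of counts in genes free of opposite-strand exon overlap, 28.7% against 21.7% to 25.5% in the other 5 libraries. Values of protein-coding genes below, and of antisense genes, are therefore uncertain as measures of the named gene's RNA.

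**Figure D1:**
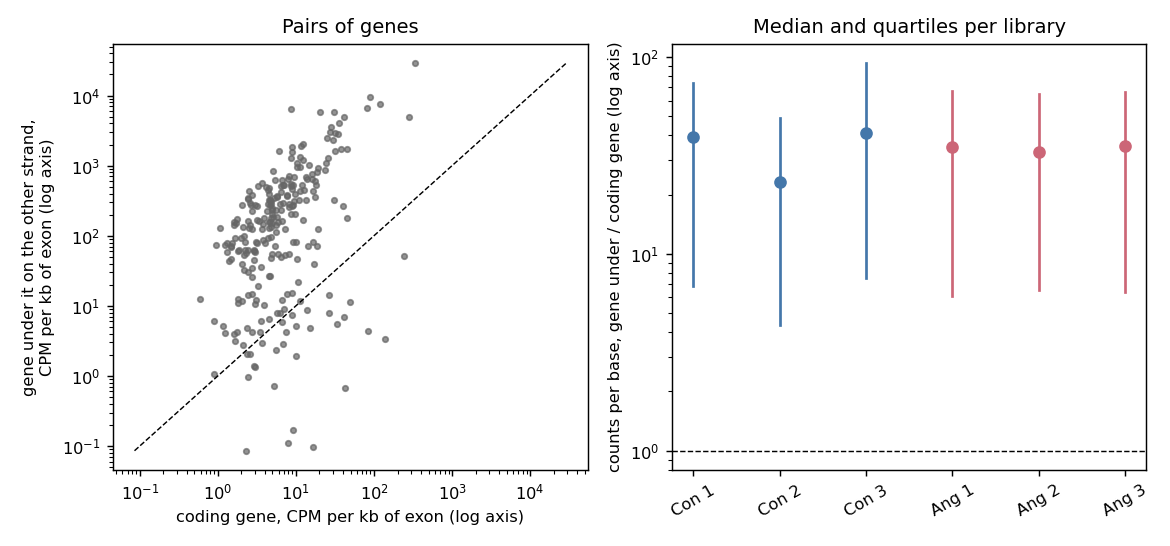
Left, CPM per kilobase of exon of 250 non-coding genes (y axis) against the protein-coding gene whose exons cover them on the other strand (x axis), mean of 6 libraries, both axes log scaled, with the dashed line at equality. Right, the median (point) and quartiles (line) over the pairs of the ratio of counts per base in each library, Con in blue and Ang in red, on a log axis, with medians of 23.2 to 41.1.

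The series design describes exposure of the breast cancer cells to vesicles of normal and of hypertrophic cardiomyocytes, and no label says how Con and Ang relate to it. No gene differed between Ang and Con past the threshold. Among 14547 tested genes, the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, and so 0 with a change of at least 2-fold, with a smallest adjusted p of 0.999. DESeq2 and limma-voom also called 0. At an unadjusted p under 0.05 edgeR counted 494 genes, 288 of them lower in Ang, where 727 would be counted by chance, DESeq2 counted 491 and limma-voom 437. All 3 Ang libraries lay on the same side of all 3 Con libraries in 8.16% of genes, against 10% by chance.

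For abundant genes the counts left little room for large differences between the 2 groups of libraries. The intervals below rest on the spread between libraries, which may be technical. They cover the counts, which are uncertain as measures of the named gene's RNA. The 95% confidence interval of the fold change lay within 2-fold in both directions for 9340 genes (64.2%), and for 3406 of the 3408 genes with a mean of at least 50 CPM. The median SE of the log2 fold change was 0.30.

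The 8 genes with the smallest unadjusted p, none past the threshold, included 6 with lower and 2 with higher values in Ang. TMEM80, a transmembrane protein gene on chromosome 11 (695428 to 705028), had 70.4 ± 4.40 CPM in Con and 42.2 ± 4.56 CPM in Ang, a log2 fold change of -0.74 ± 0.20. CDSN, the corneodesmosin gene on chromosome 6 (31115090 to 31120446), had 31.7 ± 3.77 and 15.8 ± 1.60 CPM, with 93.8% of its exon bases under exons of PSORS1C1 on the other strand. DTD2, a D-aminoacyl-tRNA deacylase gene on chromosome 14 (31446036 to 31457510), had 9.66 ± 0.324 and 2.61 ± 1.08 CPM (-1.88 ± 0.52). PLAC4, an antisense gene on chromosome 21 (41175231 to 41186788), had 9.39 ± 2.62 and 2.37 ± 1.31 CPM (-1.96 ± 0.54). HNRNPA1P59, a processed pseudogene on chromosome 1 (202911812 to 202912729) that can share reads with its parent gene, had 15.2 ± 5.71 and 5.42 ± 0.728 CPM (-1.46 ± 0.40).

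NIM1K, a protein kinase gene on chromosome 5 (43192071 to 43280850), had 59 counts over the Con libraries and 4 over the Ang libraries. The depth-scaled ratio was 0.0836, with an exact interval of 0.0221 to 0.226 for counting error. On the higher side, SEZ6L2, a membrane protein gene on chromosome 16 (29871159 to 29899547), had 6.48 ± 2.14 CPM in Con and 16.1 ± 5.81 CPM in Ang (1.28 ± 0.38). ATP6AP1, which encodes an accessory subunit of the vacuolar proton pump on chromosome X (154428632 to 154436516), had 15.5 ± 2.31 and 29.9 ± 3.78 CPM (0.94 ± 0.28). Leaving out Con replicate 2 gave 40 genes past the threshold, 20 higher and 20 lower in Ang, of which 11 changed at least 2-fold. Among them were CDSN (-1.09 ± 0.27) and HNRNPA1P59 (-1.75 ± 0.40). Leaving out Con replicate 1 gave 1, the signal recognition particle RNA gene RN7SL1, lower in Ang by 1.80 on the log2 scale and chosen after its value was seen.

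**Figure D2:**
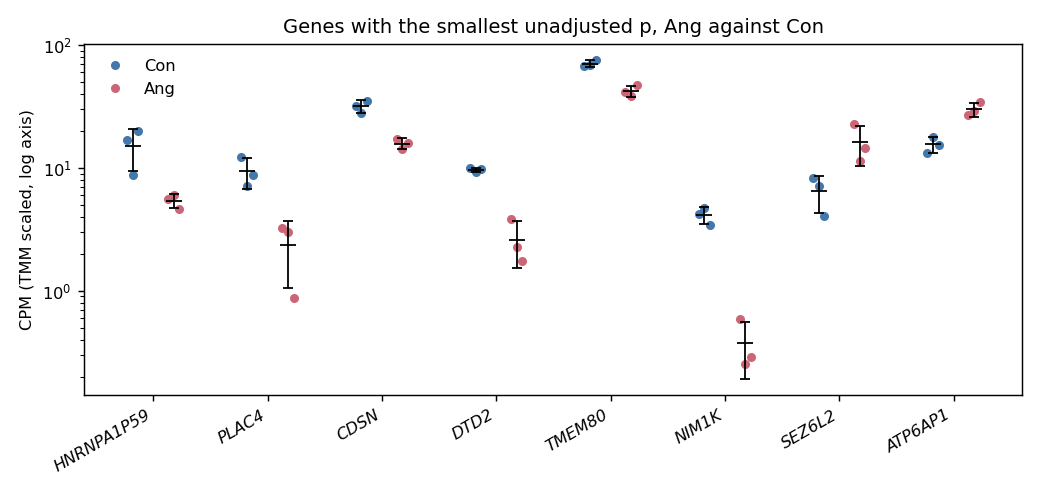
TMM-scaled CPM (y axis, log scale) of the 8 genes with the smallest unadjusted p, for each Con library (blue) and Ang library (red), with the mean and SD of each group in black. TMEM80 sits at 70.4 in Con and 42.2 in Ang on average, and no gene passed the threshold.

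Of the 33 gene lists tested, camera at the preset correlation called 1, the ribosomal proteins, higher in Ang. The shift was small. In all, 42 of 51 members had a positive log2 fold change, with a median of 0.10, and 0 members passed the threshold over all genes or adjusted over the list alone. The camera adjusted p was 0.00713, and the adjusted p was 0.930 with an estimated correlation and 0.956 by fry. RPL3 had 348 ± 99.9 CPM in Con and 405 ± 4.50 CPM in Ang (0.22 ± 0.17), RPL23 had 240 ± 22.9 and 280 ± 6.06 CPM (0.22 ± 0.17), RPL10A had 224 ± 41.8 and 261 ± 8.86 CPM (0.22 ± 0.17), and RPS15 had 111 ± 25.4 and 131 ± 34.8 CPM (0.24 ± 0.18). Without Con replicate 2, RPL3 alone of these passed the threshold, at 0.47 ± 0.11 (adjusted p 0.0452). The mean log2 CPM of the list was 8.06, 8.28 and 7.82 in Con replicates 1 to 3, and 8.10, 8.20 and 8.18 in Ang replicates 1 to 3. The highest value was in Con replicate 2, which had the lowest strand ratio, and the lowest in Con replicate 3, which had the highest. The call ended without Con replicate 3, without Ang replicate 2 or without Ang replicate 3, and 15 lists were called at the preset correlation, all higher in Ang, without Con replicate 2. With an estimated correlation 0 lists were called without Con replicate 2 (smallest adjusted p 0.314), and 0 at the preset correlation when a strand ratio term was added to that fit.

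**Figure D3:**
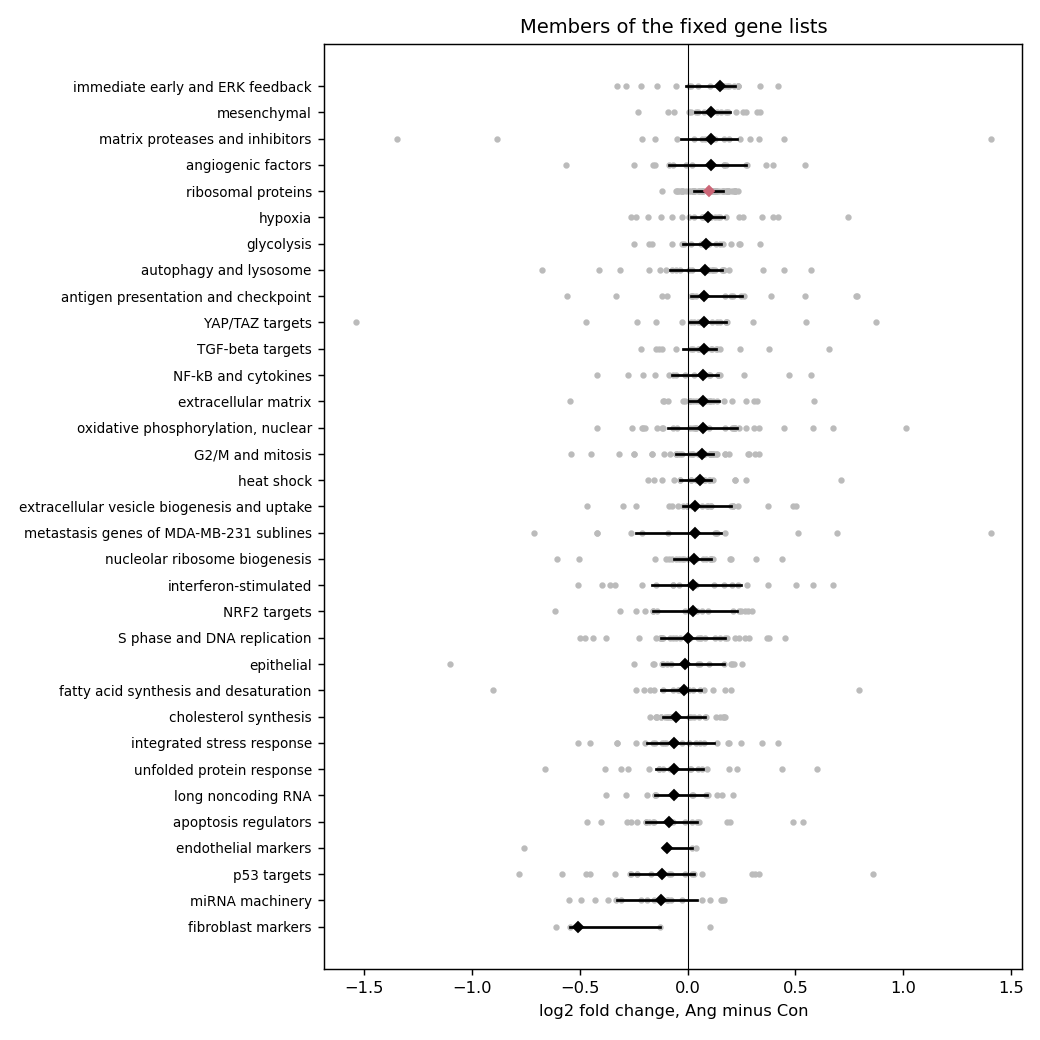
Log2 fold changes, Ang minus Con (x axis), of the tested members of the 33 gene lists (rows), with each member as a grey point, the quartiles as a line and the median as a diamond. The red diamond marks the ribosomal proteins, the list called by camera at the preset correlation, with a median of 0.10.

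No list on invasion, matrix or adhesion was called. The mesenchymal genes had 17 of 20 positive values and a median of 0.11 (camera adjusted p 0.175). FN1, the fibronectin gene, had 312 ± 52.8 CPM in Con and 377 ± 13.3 CPM in Ang, and LOXL2, a collagen cross-linking enzyme gene, had 124 ± 43.8 and 148 ± 5.79 CPM (0.26 ± 0.18). Without Con replicate 2, LOXL2 rose to 0.60 ± 0.14 and passed the threshold (adjusted p 0.0452). In the epithelial list 8 of 17 values were positive, with a log2 fold change of -1.10 ± 0.69 for MUC1. The extracellular matrix genes had 18 of 24 positive values (adjusted p 0.175), among them NID1 at 0.59 ± 0.33 and COL6A2 at 0.31 ± 0.18. Matrix proteases and inhibitors had 13 of 18 positive values (adjusted p 0.251). MMP1, the interstitial collagenase gene, had a log2 fold change of 1.41 ± 0.69 with 5.39 ± 3.47 CPM in Ang, and it is also in the list of metastasis genes of MDA-MB-231 sublines, where 9 of 15 values were positive. NEDD9, a focal adhesion scaffold gene of that list, had a log2 fold change of -0.71 ± 0.30. TGF-beta targets had 14 of 19 and YAP/TAZ targets 15 of 20 positive values, with LTBP3 at 0.38 ± 0.18 and FJX1 at -1.54 ± 0.54.

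Immune, inflammatory and stress lists were not called either. The antigen presentation and checkpoint genes came nearest, with 15 of 19 positive values, a median of 0.08 and a camera adjusted p of 0.0964. TAP2, a peptide transporter gene, had 8.65 ± 1.70 CPM in Con and 14.9 ± 2.89 CPM in Ang (0.79 ± 0.36). Interferon-stimulated genes had 11 of 20 and NF-kB and cytokine genes 12 of 20 positive values. The p53 targets had 7 of 21 positive values, with FAS, a death receptor gene, at 0.86 ± 0.33 and RRM2B at -0.58 ± 0.28. Integrated stress response genes had 10 of 22, unfolded protein response genes 9 of 20, heat shock genes 13 of 19 and NRF2 targets 10 of 18 positive values.

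Metabolic and growth lists likewise gave no call. Hypoxia genes had 20 of 26, glycolysis genes 14 of 20 and nuclear oxidative phosphorylation genes 21 of 31 positive values, with adjusted p of 0.192, 0.192 and 0.175 by camera. COX6C, a cytochrome c oxidase subunit gene, had a log2 fold change of 0.58 ± 0.25. Cholesterol synthesis genes had 11 of 23 and fatty acid genes 8 of 20 positive values. S phase genes had 16 of 33 and G2/M genes 25 of 39 positive values, with MCM6 at 0.38 ± 0.24 and PSRC1 at -0.54 ± 0.29. Apoptosis regulators had 7 of 21, autophagy and lysosome genes 15 of 24, immediate early and ERK feedback genes 15 of 20, angiogenic factors 10 of 17, nucleolar ribosome biogenesis genes 13 of 23 and long noncoding RNA genes 7 of 15 positive values. The camera direction was up while the median was below 0 for the S phase, epithelial and cholesterol synthesis lists, and up with a mean below 0 for NRF2 targets.

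The lists closest to the study's vesicles and microRNAs showed no call. Vesicle biogenesis and uptake genes had 16 of 25 positive values, with CD9, a tetraspanin of vesicle membranes, at 38.2 ± 13.1 CPM in Con and 54.7 ± 5.69 CPM in Ang (0.50 ± 0.22). The microRNA machinery genes had 5 of 18 positive values, a median of -0.13 and a camera adjusted p of 0.327, with TUT7 at -0.31 ± 0.25 and TNRC6A at -0.33 ± 0.26. Of the renin-angiotensin genes, AGT, the angiotensinogen gene, had 104 ± 24.4 and 86.3 ± 10.4 CPM (-0.27 ± 0.18), ATP6AP2, the prorenin receptor gene, -0.25 ± 0.21, LNPEP 0.04 ± 0.22 and AGTRAP -0.00 ± 0.50, and 4 tested members were too few for a list test. Among 4 tested replication-dependent histone genes, H2AC6 alone passed when adjusted over the list alone (adjusted p 0.0307 by edgeR) and not over all genes. It had 46 counts over the Con and 6 over the Ang libraries, a ratio of 0.161 with an exact interval of 0.0561 to 0.378 for counting error.

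Markers of other cell types were few. Tested members numbered 2 of 26 for cardiomyocytes, 5 of 18 for fibroblasts, 2 of 16 for leukocytes and 5 of 13 for endothelium, and neither list with 5 tested members was called (camera adjusted p 0.413 for fibroblasts and 0.638 for endothelium). TTN and NPPA, the tested cardiomyocyte markers, had log2 fold changes of -0.17 ± 0.17 and -0.34 ± 0.40. Exons on the other strand overlap 15.5% of the exon bases of TTN and 25.5% of those of NPPA, so their counts may not be their own RNA. Of the 13 mitochondrially encoded genes listed, 0 were matched in the files, so they could not be analysed here.

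The series design states the search for targets of microRNAs as the aim, and genes with seed sites were therefore compared with genes without one. No seed was called. Over 27 seeds, 11051 tested genes with a 3′ untranslated region entered, and the smallest camera adjusted p was 0.713. The median log2 fold change of site genes was below that of the other genes for 23 of 27 seeds, with differences from -0.038 to 0.0081. With length and GC content of the 3′ untranslated region regressed out, site genes lay lower for 16 seeds and higher for 11. Genes with a site of miR-200b/c-3p lay lowest against other genes, by -0.038 over 2955 site genes. The median of these site genes, -0.024, was at the 20.8th percentile of the medians of random 7-mers. Site genes of miR-21-5p lay lower by -0.030 over 1694 genes and of miR-133a-3p, a microRNA of heart muscle, by -0.013 over 1833 genes. Only let-7-5p fell under the 5th percentile, at 2.0, with a camera adjusted p of 0.856. A shift of -0.2 given to the miR-21-5p site genes was called in each of 5 simulations, in which genes varied independently of each other.

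**Figure D4:**
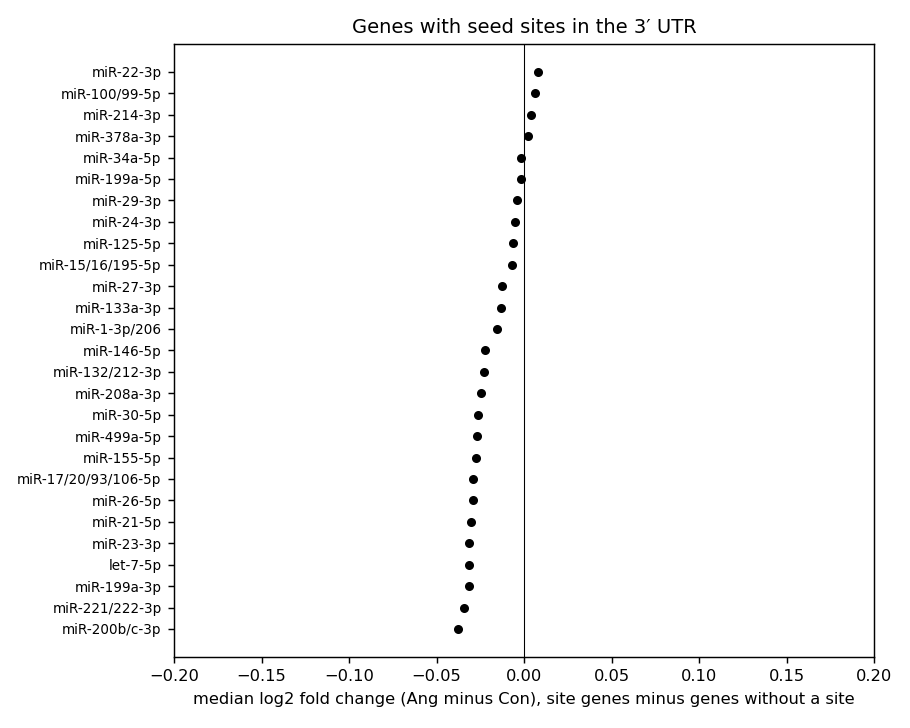
Difference of the median log2 fold change (Ang minus Con) between genes with and without a 3′ untranslated region seed site (x axis) for 27 microRNA seeds (rows). The differences run from -0.038 to 0.0081 and none was called.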

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

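The alternatives planned before the data were examined left the 0 called genes at 0 under RLE scaling, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 and limma-voom, and the unadjusted counts at p under 0.05 ran from 437 to 827. Leaving out 1 library gave 0 to 40 genes, 0 to 11 of them at least 2-fold, with 40 without Con replicate 2 and 1 without Con replicate 1. The cause was not tested for Con replicate 1. Called lists numbered 1 at first, 2 with the CPM filter (mesenchymal joined, 0 lists in that fit with an estimated correlation), 0 with an estimated correlation, 0 by fry, and 0 to 15 leaving out 1 library, with 15 without Con replicate 2 (0 with an estimated correlation) and 0 without Con replicate 3, Ang replicate 2 or Ang replicate 3. The estimated correlation of the ribosomal protein list was 0.741, against the preset 0.01. Seeds called stayed at 0 in each setting run. As for a replicate block, Con and Ang libraries of the same number had correlations of deviations of 0.037, 0.068 and 0.036. The other pairs of a Con and an Ang library had -0.070 to 0.030. These values are all small, so a weak pairing by number is neither shown nor excluded. The block gave 0 genes, 0 at least 2-fold, 1 list and 0 seeds. Chosen after seeing the data, the strand ratio term gave 4 genes (among them CSF1, ATL1 and MTRNR2L8, named after their values were seen), 0 at least 2-fold, and 8 lists, all higher in Ang (0 with an estimated correlation). Genes free of opposite-strand overlap gave 0 genes and 3 lists (hypoxia, glycolysis and ribosomal proteins, 0 with an estimated correlation). Library quality weights, 0.416 for Con replicate 2 and 0.936 to 1.43 for the others, gave 1 gene (MTND6P4). Con replicate 2 left out with the strand ratio term gave 1 gene (SOWAHD), which was at least 2-fold, and 0 lists. The fitted log2 fold change of SOWAHD was extreme, at -15.5 ± 2.69. It came from 5 libraries with a term that had a correlation of -0.94 with group, so its size is uncertain. The cause was not tested for these counts. Of the named genes' alternative values, 1345 kept direction and side of the threshold, 47 changed sign without a call and 7 passed the threshold in the same direction. In the simulations 44.2% of 2-fold changes were called over all genes and 93.8% among genes of at least 50 CPM. Changes of 2-fold in low genes would thus often be missed. Depth itself was not varied there.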

Other observations

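Tests of the strand-marked and unmarked explanations, list tests with an estimated correlation in refitted models, the simulations of a strand ratio effect, the strand ratio term in the models, the repeat draws of thinned counts, the setting of margins against their SE, and the pairs of covered genes were chosen after results were seen. The genes lying under coding exons were looked at on their own, since 88.8% of the pairs had more counts per base in the covered gene. Of 250 pairs, 218 covered genes were tested, and the edgeR quasi-likelihood test adjusted over these genes called 0, with a smallest adjusted p of 0.947 and 5 at an unadjusted p under 0.05. Their median log2 fold change was 0.04 with a median SE of 0.18, and the 95% interval lay within 2-fold for 178 (81.7%). The genes under GAPDH, TPT1, P4HB and UBB, a ubiquitin gene, had log2 fold changes of 0.17 ± 0.19, 0.05 ± 0.18, 0.11 ± 0.18 and 0.10 ± 0.18. Across the 218 pairs, which are not independent replicates, the fold changes of the covered gene and its coding gene had a Spearman correlation of 0.085.

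Without Con replicate 2, the 20 genes called higher in Ang included CD74, the invariant chain of class II antigen presentation (0.57 ± 0.14), the growth factor genes CSF1 (0.70 ± 0.14) and HBEGF (0.93 ± 0.22), IGFBP4 (0.72 ± 0.15), the iron storage gene FTL (0.53 ± 0.11) and the metallothionein gene MT1E (1.86 ± 0.44). Over all 6 libraries these log2 fold changes were 0.41, 0.51, 0.56, 0.30, 0.25 and 0.89, none past the threshold. The 20 called lower included ATL1 (-0.76 ± 0.14), the DNA methyltransferase gene DNMT3A (-1.60 ± 0.37) and the Wnt receptor gene FZD4 (-0.53 ± 0.13), against -0.59, -1.25 and -0.37 over all 6. These were picked after their values were seen. Of the 40 genes 18 (45.0%) were free of opposite-strand exon overlap, against 48.0% of the genes tested. The directions differed, with 14 of the 20 higher and 4 of the 20 lower genes free of it. The antisense genes called were all among the lower ones, such as RAD21-AS1 (-0.58 ± 0.14) and ENSG00000255252 (-0.40 ± 0.10), the latter with 100% of its exon bases overlapped. Of the coding genes named here, ATL1 and FZD4, both lower, had 22.6% and 18.9% of exon bases overlapped. DNMT3A and the higher genes named had 0%.

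The first pattern is that genes under coding exons on the other strand hold more counts per base than the coding gene. Transcription of the antisense genes themselves is argued against, since antisense genes at least 90% covered held 156 times the counts per base of those with no overlap. Libraries without strand marking are argued against too, as reads would then split evenly or be dropped, whereas the 25th percentile of the ratio over pairs was 5.86. Strand-marked libraries counted with the opposite setting remain a candidate explanation, as a hypothesis without independent support, since the lowest library median ratio of 23.2 only restates the pattern. The labels' protocol names no strand-marking step and the strand setting is not given in the sources used here, so this stays open. No explanation by the groups was tested for this pattern.

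The second pattern is that 40 genes passed without Con replicate 2 and 0 with it. With the strand ratio in the model of the 5 libraries, the median absolute log2 fold change of these genes was 0.829 of its value without (0.59 against 0.71), and 37 of 40 kept their sign. The mean of the 40, each turned to its direction, went from 0.92 ± 0.03 to 0.85 ± 0.08 over libraries. The genes and their directions were chosen in these same libraries, so the SEs of this mean are too small by selection. The median SE of single genes grew from 0.15 to 0.41, as the ratio has a correlation of -0.94 with group there, and 0 of the 40 were called. The fraction is above the bound of 0.5 set beforehand, but that bound was wrong, since genes called for a tight group difference keep much of it by selection. In 20 simulations of these libraries in which the strand ratio alone moved the genes, 17 also kept 0.5 or more (median 0.591). None of the 20 reached 0.829, the highest being 0.739, nor the share of signs kept. This decides nothing, since it depends on the simulated effect sizes, which were drawn without regard to opposite-strand overlap. The simulations called 38 to 112 genes (median 65.5) against 40 here. A first trial with smaller effects, not kept, reached fractions above 0.829 in some runs. Overlap also went with direction, as 14 of the 20 higher and 4 of the 20 lower genes were free of opposite-strand exon overlap. The Con libraries left had higher strand ratios, 39.3 and 41.1 against 32.9 to 35.4 in Ang. These values go with a difference in opposite-strand counts. Such a difference cannot be told apart here from a difference between groups. Thinning the 5 libraries to 3369212 counts each left 19 genes in the first draw, under the bound of 20 set beforehand. Over 20 draws it left 15 to 70, with 14 draws at 20 or more. Genes passed at equal totals in each draw, so a difference in depth does not account for all of the calls. Thinning also removes counts whatever the cause, so a part played by depth stays open. A response to the exposure is untested, since removing a library on its values is not a design of the study.

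The third pattern is the ribosomal protein list, higher in Ang by camera at the preset correlation. With the strand ratio in the model the median of the list was 1.33 times its value without. The list was still called by camera (adjusted p 4.7e-07 with the term and 0.00713 without). That is the outcome predicted if the strand ratio was not the cause. The test had little room for another, since the Con ratios (39.3, 23.2 and 41.1) lay on both sides of the Ang ratios. A trend with the strand ratio over the 6 libraries is therefore not decided by it. The difference itself was uncertain, as the mean of the list over libraries was 0.12 ± 0.08 higher in Ang with that term and 0.11 ± 0.14 without. With an estimated correlation the list was not called in either fit (adjusted p 0.552 and 0.930). In the 5 libraries without Con replicate 2 the term took this mean from 0.22 ± 0.10 to -0.08 ± 0.26 and ended the call. There the 2 Con libraries have the highest ratios, so the term shares its variation with the groups and the SE grew, and a part played by opposite-strand counts is not excluded. The list was called in 3 of the 6 fits that left out 1 library, so a call that single libraries decide may account for it. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and the real split gave 0 genes and the highest of the others 1. At an unadjusted p under 0.05 the real split counted 494 genes. Other splits counted fewer (337, 418, 438, 456 and 481) or more. The splits that set Con replicates 1 and 3 against Con replicate 2 counted the most, at 1673, 1334 and 816. The largest counts thus set Con replicate 2 apart from the other Con libraries and do not follow the groups.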
